A study of Danio rerio with 3 samples.

How the data were processed

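Single-cell RNA libraries were made from EGFP-positive cells sorted from dissociated Tg(olig2:EGFP) zebrafish embryos with the 10x Chromium system, which tags each RNA molecule at its 3' end with a cell barcode and a UMI, per the labels' protocols. There were 3 libraries, 1 each at 24, 36 and 48 hpf, grouped by the stage given in the labels. The series is a reanalysis of an earlier data set, per the labels. Cell Ranger, Seurat and the genome build GRCz11 are named in the submitters' processing notes, and their versions and settings are not given in the sources used here. The source is named in the labels as spinal cord cells.

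The files used were tables of cells, 1 per stage and 1 integrated table over the 3 stages, and they held no values per gene, so the lists of cell type marker genes fixed beforehand could not be used and cell types were taken from the deposited class names. The UMIs and the detected genes per cell are counts that the authors deposited without normalisation. The mitochondrial share is a percent deposited per cell, with a largest value of 4.995%, and the fewest UMIs in a cell were 504, so cells had been filtered before deposit. The S and G2M values are scores deposited per cell, relative to the set of cells scored together, and gene lists are not given in the sources used here. In all 6264 cells of both kinds of table the deposited phase followed the higher score, with G1 where neither was above 0. The scores of the same cell differed between its stage table and the integrated table in every cell, and how each set was computed is not given in the sources used here. All 6264 cells were in both kinds of table with equal UMI counts, matched by barcode and stage. How doublets were treated is not given in the sources used here, and no doublet caller could be run without values per gene.

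Shares of cells were computed per stage for each of the 28 classes of the integrated annotation, where the class MEP Glia is split from CMN Precursor, and for groups of classes. Each share has an exact (Clopper-Pearson) 95% binomial interval. Ratios of shares have exact conditional intervals for 2 counts, and for the size rule a count of 0 was replaced by a floor of 3 cells of that library. The intervals and floors cover counting error only, not differences between embryos or libraries. With 1 library per stage no test between stages was possible and no p-value was computed. A share was called higher or lower between 2 stages only if the ratio was at least 2 and the intervals did not overlap. Classes named in the text were those with at least 1% of the cells of any stage, each given for the stages of its highest and lowest share, which left out only FP. The shares of cells called S or G2M were computed over all cells and within classes of at least 50 cells at each stage compared, and a class below that at other stages is given only where it passed. Median UMIs and genes per cell, and the share of cells with the same name in both tables, were also computed. The size rule and the intervals of single shares were tested on simulated cells of 25 classes (100 simulations per ratio). With no true change 0.12% to 0.2% of the simulated comparisons were called, at a true ratio of 2 the rule called 47.4% to 50.5%, and at a true ratio of 3 it called 99.4%. The simulated cells varied by counting error only, so these rates leave out differences between embryos, sorts or libraries. The intervals held the true share in 95% to 96.0% of the simulations. The early share of each simulated class was its share of all cells, at least 1%. Early shares near 0, the floor, true falls and the intervals of ratios were therefore not tested.

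Alternatives fixed before the data were examined were cells with at least 2000 UMIs, leaving out the 5% of cells with the most UMIs, cells with at most 3% mitochondrial reads, the annotation of the stage tables, neural or glial classes as the denominator, cells matched on UMI depth in 20 bins of log UMI count (875 cells per stage), phase calls only where the higher score was above 0.1, phase calls of the stage tables, and each progenitor class on its own. Thinning cells to a fixed number of UMIs would need values per gene, so matching stood in its place. Alternatives chosen after seeing the data were MEP Glia inside CMN Precursor, the progenitor classes with NP, Pre-OPC and OPC added, the stage-table calls with a score above 0.1, and the MN share without MN5. Barcodes of 16 bases were compared between libraries by their first 7 bases. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 (adjusted Rand index) and matplotlib 3.10.9.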

Results

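The data were single-cell RNA profiles of cells sorted for green fluorescence from wild-type zebrafish embryos carrying the olig2:EGFP transgene. The transgene is used to mark the pMN domain of the ventral spinal cord and the cells that descend from it. The deposited class names also include Retinal Progenitor, Lateral FP, V3 IN, NM Progenitor and Mes1. By these names not all sorted cells were of the pMN lineage or of the spinal cord. The pMN domain is the progenitor zone that makes motor neurons first and cells of the oligodendrocyte lineage afterwards. Cells came from 3 stages, 24, 36 and 48 hours post fertilisation (hpf), with 1 library per stage, so no value has a replicate. The question was how the make-up of this sorted population changed over the stages.

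The 24 hpf library held 1826 cells and 16432785 UMIs (unique molecular identifiers, counts of single RNA molecules), the 36 hpf library 2044 cells and 10656224 UMIs, and the 48 hpf library 2394 cells and 17562789 UMIs. The median cell had 8935.5 UMIs at 24 hpf (interquartile range 6591.5 to 11564), 4569 at 36 hpf (3541 to 6316.5) and 5774.5 at 48 hpf (4223 to 8488). Median detected genes per cell were 2049, 1349 and 1941 at the 3 stages, and median mitochondrial shares were 0.686%, 1.06% and 2.35%. At a like depth of 5000 to 6000 UMIs, the median cell had 1536 detected genes at 24 hpf (87 cells), 1506.5 at 36 hpf (256 cells) and 1813 at 48 hpf (336 cells). The 48 hpf library also stood apart in its cell barcodes: 87.0% of its 2394 cells had a start of 7 bases that occurred in no cell of the other libraries, whereas 97.4% of the 36 hpf cells had a start found at 24 hpf. Every difference between 48 hpf and an earlier stage is therefore also a difference between barcode sets.

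The pMN classes made up a smaller share of the cells at 48 hpf than at either earlier stage. Cells of the classes pMN1, pMN2 and pMN3 were 31.1% of the 24 hpf library (567 cells, exact 95% binomial interval 28.9 to 33.2), 20.4% at 36 hpf (417 cells, 18.7 to 22.2) and 7.02% at 48 hpf (168 cells, 6.03 to 8.12). The share at 48 hpf was 4.42-fold lower than at 24 hpf (95% interval of the ratio 3.72 to 5.29) and 2.91-fold lower than at 36 hpf (2.42 to 3.50). The 3 classes differed in size of change. pMN3 went from 11.6% at 24 hpf to 0.543% at 48 hpf, a 21.4-fold lower share (12.2 to 40.8), and was already 2.50-fold lower at 36 hpf (1.95 to 3.22). pMN1 went from 12.6% to 2.30%, which was 5.48-fold lower (4.07 to 7.50). pMN2 had its highest share, 7.00%, at 36 hpf and its lowest, 4.18%, at 48 hpf, a difference below the 2-fold size used for calls. The ratio of the whole pMN share at 36 over 24 hpf was also below that size, with a log2 of -0.61, and among cells matched on UMI depth its direction turned, to 0.61. By the names of the stage tables, pMN cells were 28.8%, 23.6% and 2.88% of the 3 libraries, so that the log2 ratio at 48 over 24 hpf was -3.32 there, -2.15 in the integrated table and -1.48 in matched cells, and that at 48 over 36 hpf -3.04 and -1.54 by the 2 annotations. All intervals here cover counting error only, and all shares are of the sorted EGFP-positive cells, not of the cord as a whole.

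Motor neuron classes made up a larger share of both later libraries than of the 24 hpf library. Cells of MN1 to MN5 were 7.78% of the 24 hpf library (142 cells, 6.59 to 9.10), 17.5% at 36 hpf (358 cells, 15.9 to 19.2) and 34.0% at 48 hpf (813 cells, 32.1 to 35.9). The 48 hpf share was 4.37-fold higher than at 24 hpf (3.65 to 5.26), and the 36 hpf share 2.25-fold higher (1.85 to 2.76). MN4 changed most among them, from 0.383% (7 cells) at 24 hpf to 8.77% (210 cells) at 48 hpf, a 22.9-fold higher share (10.9 to 57.6). MN3 went from 0.219% to 2.59% (11.8-fold higher, 4.39 to 44.8), MN5 from 1.59% to 9.94% (6.26-fold higher, 4.25 to 9.55) and MN1 from 2.35% to 6.64% (2.82-fold higher). The stage tables gave MN5 cells different names by stage. At 24 hpf 27 of 29 were GABAergic IN there, and at 48 hpf 223 of 238 were MN4. Without MN5 the MN share was 3.88-fold higher at 48 than at 24 hpf (3.17 to 4.79). MN2 had its lowest share, 3.23%, at 24 hpf and its highest, 6.12%, at 36 hpf, which did not reach the size for a call. The class named Pre-MN was 2.41% at 24 hpf and 6.73% at 48 hpf, 2.79-fold higher (1.99 to 3.99), a call that ended in cells matched on UMI depth. The order of the Pre-MN shares depended on the annotation, because the stage tables gave that name to 9.75% of the 24 hpf cells, 6.65% of the 36 hpf cells and 6.27% of the 48 hpf cells. Among cells matched on UMI depth, the log2 ratio of the MN share at 36 over 24 hpf was 0.42 (1.17 in all cells) and was no longer called, whereas that at 48 over 24 hpf was 1.87 (2.13 in all cells).

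Oligodendrocyte lineage classes changed in kind more than in their joint share. Pre-OPC, OPC and Pre-OL cells together, where an OPC is an oligodendrocyte precursor cell and OL stands for oligodendrocyte, were 11.4% of the 24 hpf library, 6.80% at 36 hpf and 8.60% at 48 hpf. Pre-OPC made up nearly all of this at the earlier stages, with 207 cells (11.3%, 9.92 to 12.9) at 24 hpf and 134 cells (6.56%, 5.52 to 7.72) at 36 hpf, and was down to 9 cells (0.376%, 0.172 to 0.712) at 48 hpf. Its 48 hpf share was 30.2-fold lower than at 24 hpf (15.6 to 66.9) and 17.4-fold lower than at 36 hpf (8.92 to 39.0). OPC cells numbered 1 at 24 hpf, 3 at 36 hpf and 127 at 48 hpf (5.30%, 4.44 to 6.28), so that the 48 hpf share was 36.1-fold higher than at 36 hpf (12.1 to 178) and 96.9-fold higher than at 24 hpf (17.1 to 3856). The 24 hpf value rests on a single cell of 913 UMIs. Without it, and with the floor of 3 cells used in place of a count of 0, the log2 ratio at 48 over 24 hpf was 4.93 among cells with at least 2000 UMIs and 5.06 by the names of the stage tables. In matched cells, which kept it, the log2 ratio was 5.93 at 48 over 24 hpf and also at 48 over 36 hpf (5.18 in all cells). Pre-OL cells numbered 0 of 1826 at 24 hpf, which allows up to 0.202% by the upper limit of the exact interval, 2 at 36 hpf and 70 at 48 hpf (2.92%, 2.29 to 3.68). By the lower limit of the exact interval of the ratio, the 48 hpf share of Pre-OL was at least 14.1-fold higher than at 24 hpf. With the floor, the log2 ratio of Pre-OL was 4.15 in all cells and 3.00 in matched cells, and that of Pre-OPC at 48 over 24 hpf, -4.91 in the integrated table, was -6.55 by the stage tables, where no 48 hpf cell had the name, and -4.32 in matched cells.

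Glial classes other than the oligodendrocyte lineage also had their highest shares at 48 hpf. RG (radial glia, the elongated neural stem cells of the later cord) numbered 1, 4 and 65 cells at 24, 36 and 48 hpf, and its 48 hpf share of 2.72% (2.10 to 3.45) was 13.9-fold higher than at 36 hpf (5.17 to 52.4). By the stage tables, where the name RG occurs only at 48 hpf, the log2 ratio with the floor was 5.96 (3.79 in the integrated table). MEP glia, cells at the motor exit points where motor axons leave the cord, numbered 3, 15 and 53 cells. Their share was 0.164% at 24 hpf and 2.21% at 48 hpf, 13.5-fold higher (4.37 to 67.4), a log2 ratio of 3.75 that was 2.50 in cells matched on UMI depth, 3.07 without the 5% of cells with the most UMIs and 4.52 by the stage tables. The 48 hpf stage table used both names for more cells, 218 for RG and 90 for MEP Glia. Only 62 of these RG and 20 of these MEP Glia cells had the same name in the integrated table, so the ratios of the 2 annotations describe mostly different cells.

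Among the interneuron classes V3 IN changed in share by the size rule. V3 IN, a class of ventral interneurons, was 1.53% at 24 hpf (28 cells), 6.95% at 36 hpf (142 cells) and 6.64% at 48 hpf (159 cells), with a 4.53-fold higher share at 36 than at 24 hpf (3.00 to 7.06). The stage tables named no 24 hpf cell V3 IN, which with the floor gave a log2 ratio of 5.29 (2.18 in the integrated table), and 23 of the 28 integrated V3 IN cells at 24 hpf were GABAergic IN there. Pre-V3 IN ranged from 0.931% at 24 hpf to 1.88% at 48 hpf and V2 IN Precursor from 0.418% at 48 hpf to 1.13% at 36 hpf, and neither met the size rule for any pair of stages in all cells. In cells matched on UMI depth the log2 ratio of V2 IN Precursor at 36 over 24 hpf was 2.17 (0.36 in all cells) and was called. In the stage tables the name V2 IN Precursor was given to 2.68% of the 24 hpf cells and to no cell of the later libraries. Cerebrospinal fluid-contacting neurons (CSF-cN), which line the central canal, showed another course, with the lowest share at the middle stage. CSF-cN1 and CSF-cN2 together were 6.13% at 24 hpf (112 cells, 5.08 to 7.33), 1.86% at 36 hpf (38 cells, 1.32 to 2.54) and 5.10% at 48 hpf (122 cells, 4.25 to 6.05). CSF-cN1 was highest at 24 hpf (4.27%) and lowest at 36 hpf (1.37%), 3.12-fold lower. CSF-cN2 was highest at 48 hpf (2.38%) and lowest at 36 hpf (0.489%), and its 48 hpf share was 4.87-fold higher (2.46 to 10.7). The CSF-cN cells of the 36 hpf library were shallow, with a median of 3273 UMIs against 7062.5 at 24 hpf and 4960.5 at 48 hpf. The log2 ratio of the CSF-cN share at 36 over 24 hpf was -1.72 in all cells and -2.51 in matched cells.

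The remaining classes had peaks at different stages. NM Progenitor was 5.26% at 24 hpf (96 cells) and 0.636% at 36 hpf (13 cells), 8.27-fold lower (4.61 to 16.1), and among cells matched on UMI depth this difference was no longer called. Its log2 ratio was -3.05 in all cells, and -4.67 with the floor by the stage tables, where the name occurs only at 24 hpf. CMN Precursor was 6.02% at 24 hpf and 0.752% at 48 hpf, 8.01-fold lower (4.84 to 14.0), a log2 ratio of -3.00 that was -1.06 with MEP Glia left inside this class and -1.17 by the names of the stage tables. CMN peaked at 36 hpf with 7.97% (163 cells) and was lowest at 24 hpf with 1.59% (29 cells), 5.02-fold higher at 36 hpf (3.37 to 7.73), a call that was lost in matched cells with a log2 ratio of 0.92 (2.33 in all cells). The stage tables named 0 cells CMN at 24 hpf and 92 at 36 hpf, with a log2 ratio of 4.78 by the floor, and 28 of the 29 integrated CMN cells at 24 hpf were CMN Precursor there. Retinal Progenitor cells were found mainly at 36 hpf, where they were 4.94% (101 cells), with 0.657% (12 cells) at 24 hpf and 0.376% (9 cells) at 48 hpf. Mes1 was lowest at 24 hpf (0.438%) and highest at 36 hpf (1.32%), 3.02-fold higher (1.33 to 7.68), by the integrated names. In the annotation of the stage tables the name Mes occurs only at 48 hpf, for 24 cells. Of the 27 integrated Mes1 cells at 36 hpf, 20 were pMN2 and 7 were V3 IN in that annotation. The highest Mes1 share at 36 hpf therefore depended on the annotation. Lateral FP, a class of the floor plate at the ventral midline, was highest at 24 hpf (10.6%) and lowest at 48 hpf (5.64%), a log2 ratio of -0.91 that was not called in all cells but was called among cells with at least 2000 UMIs (-1.05) and without the 5% of cells with the most UMIs (-1.01). The NP classes together held a near constant share in the integrated table, 12.4%, 12.4% and 12.6%, in which NP1 ranged from 4.87% at 24 hpf to 8.48% at 48 hpf and NP2 from 4.14% at 48 hpf to 7.50% at 24 hpf. By the names of the stage tables NP cells were 7.12%, 9.98% and 7.85% at the same stages. In cells matched on UMI depth the NP share was lower at 36 than at 24 hpf, with a log2 ratio of -1.51.

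**Figure D1:**
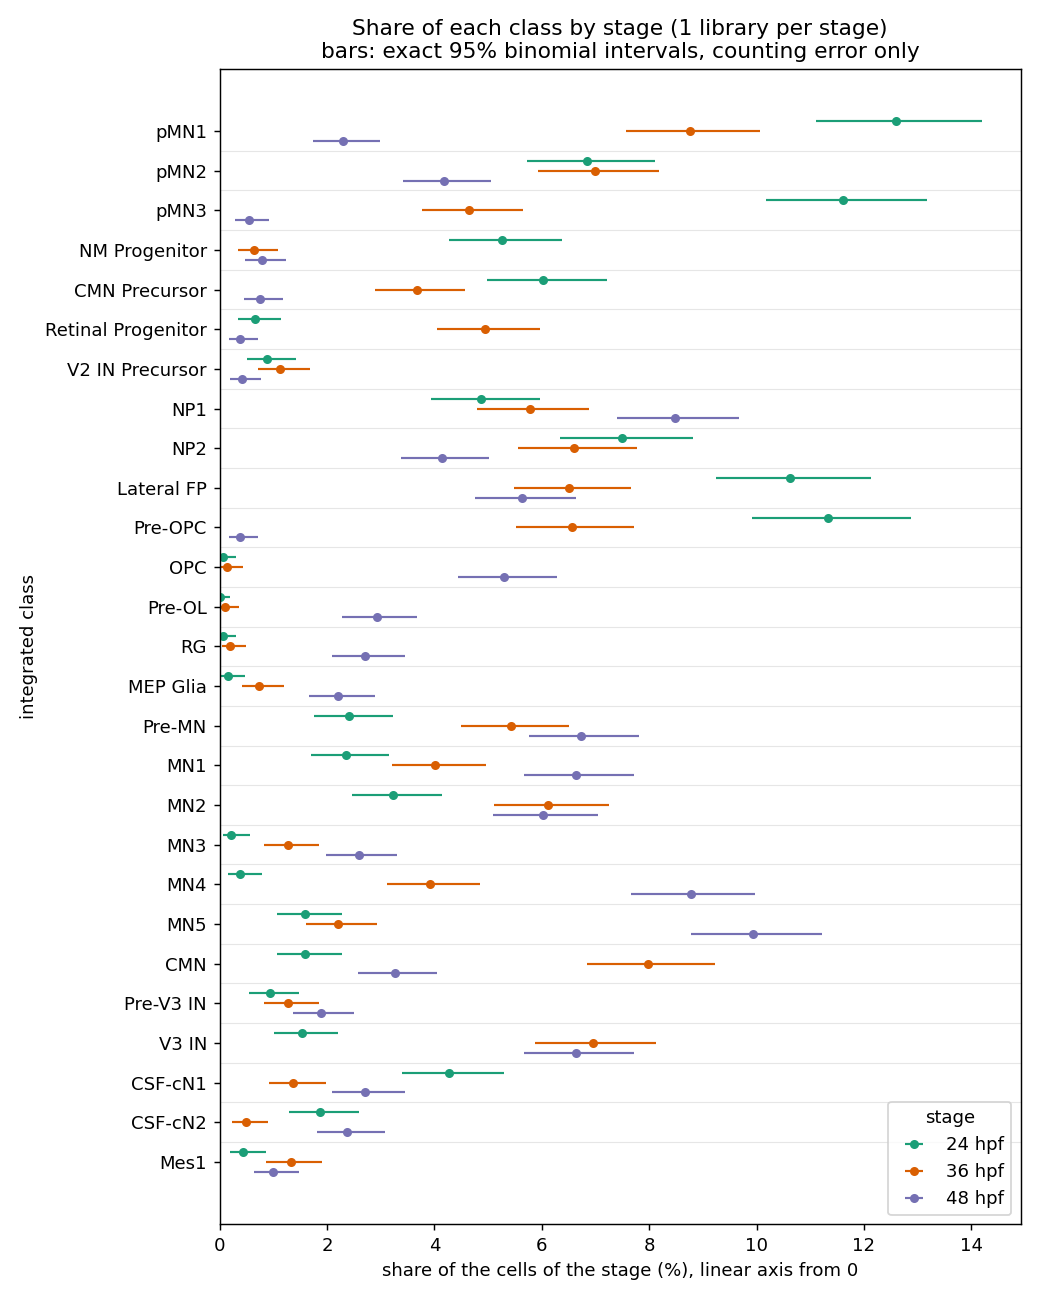
Share of the cells of each stage (in percent, x axis) for the 27 classes of the integrated annotation that reached 1% at any stage (y axis); points are the shares in the 24, 36 and 48 hpf libraries (1 per stage) and bars are exact 95% binomial intervals, which cover counting error only. The pMN1, pMN3 and Pre-OPC points move left with stage, those of MN4 and MN5 move right to 8.77% and 9.94%, and OPC, Pre-OL and RG lie near 0 before 48 hpf.

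Counted over these 27 classes, 7 had a higher and 4 a lower share at 36 than at 24 hpf, and 16 met neither. From 24 to 48 hpf the counts were 11 higher (CMN, MEP Glia, MN1, MN3, MN4, MN5, OPC, Pre-MN, Pre-OL, RG and V3 IN) and 5 lower (CMN Precursor, NM Progenitor, Pre-OPC, pMN1 and pMN3). From 36 to 48 hpf they were 8 higher and 6 lower. Counted by names without closing numbers, cells matched on UMI depth kept 3 of 6 higher and 1 of 2 lower calls at 36 over 24 hpf. The calls of MN, CMN and NM Progenitor (log2 ratio of -1.29) ended there and that of Pre-MN turned, from 1.17 to -0.12. Matching also ended the calls of CMN and Pre-MN at 48 over 24 hpf (0.45 and 0.97) and of MEP Glia and CMN at 48 over 36 hpf (0.63 and -0.47). The call of CMN at 48 over 24 hpf was also lost without the 5% of cells with the most UMIs (0.96) and over neural or glial classes only (0.98), and that of Mes1 at 36 over 24 hpf was lost without the deepest cells (1.01). With MEP Glia left inside CMN Precursor, the lower share of that class at 48 than at 36 hpf was no longer called (-0.57). A class counted here had a ratio of shares of at least 2 and intervals that did not overlap, and no p-value was computed, since cells of a single library are not replicates.

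Cells called S or G2M, the phases of DNA synthesis and of division, made up their smallest share at 48 hpf. They were 65.8% of the 24 hpf cells (1202 cells, 63.6 to 68.0), 38.6% of the 36 hpf cells (790 cells, 36.5 to 40.8) and 20.1% of the 48 hpf cells (481 cells, 18.5 to 21.8) by the calls of the integrated table. S calls went from 33.8% to 17.7% and 11.4%, and G2M calls from 32.0% to 20.9% and 8.73%. The calls of the stage tables gave 62.9%, 37.7% and 33.4%. The tables gave the same phase to 91.9% of the 24 hpf cells and 96.8% of the 36 hpf cells, but to 73.8% of the 48 hpf cells, where 329 of the 1913 cells called G1 in the integrated table were called S and 119 were called G2M in the stage table. Cells called S or G2M had more UMIs than G1 cells within each library, with medians of 10172 against 7294 at 24 hpf, 6518 against 4016.5 at 36 hpf and 7784 against 5454 at 48 hpf. When the libraries were matched on UMI count, the shares were 55.3%, 59.7% and 23.4%, so the order of 24 and 36 hpf turned and the lowest share stayed at 48 hpf.

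The pMN and the motor neuron classes stood far apart in their calls. Of the cells in the pMN classes, 99.5% were called S or G2M at 24 hpf, 97.6% at 36 hpf and 98.8% at 48 hpf, and no cell of pMN1 or pMN2 was called G1 at any stage. By the stage tables the pMN classes were at 95.6%, 97.4% and 97.6%. Motor neuron classes were the reverse, with 1.41% (2 of 142 cells), 2.51% (9 of 358) and 0.615% (5 of 813). Neurons that have left the cell cycle give the level at which these calls come up without division, and by the stage tables this level was 2.11%, 3.07% and, at 48 hpf, 18.9% (154 of 813, 16.3 to 21.8) in the same cells. Among the motor neuron classes the 48 hpf level of the stage table ran from 9.05% in MN4 to 32.4% in MN5, and Pre-MN was at 35.4%. Lateral FP changed over the stages in both sets of calls, from 78.9% (72.4 to 84.4) to 43.6% (35.0 to 52.5) and 21.5% (14.9 to 29.4) by the integrated table and from 82.0% to 45.1% and 13.3% by the stage tables. Pre-OPC cells called S or G2M were 84.5% (78.9 to 89.2) at 24 hpf and 51.5% (42.7 to 60.2) at 36 hpf. In NP1 the shares were 64.0%, 38.1% and 40.4%, and in NP2 they were 8.03%, 4.44% and 0%, where 0 of 99 cells at 48 hpf has an upper limit of 3.66%. The stage tables gave NP1 47.2%, 32.2% and 60.1% and NP2 1.46%, 1.48% and 49.5%, so the order of the stages in both classes depended on which calls were used. Median UMIs at 24 and 36 hpf were 8636.5 and 4637 in Lateral FP, 8904 and 4892 in Pre-OPC, and 6146 and 3807 in NP1. Cells called S or G2M were the deeper ones in each library, and these classes were not matched on depth. Depth therefore stays open for their lower values at 36 hpf. Of the 127 OPC cells at 48 hpf, 12 were called S or G2M (9.45%, 4.98 to 15.9) and of the 70 Pre-OL cells none was, whereas 64 of the 65 RG cells were. The stage table called 41 of the same OPC cells (32.3%), 8 of the Pre-OL cells and 14 of the RG cells (21.5%), and the OPC value is no higher than that of MN5 in the same table.

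**Figure D2:**
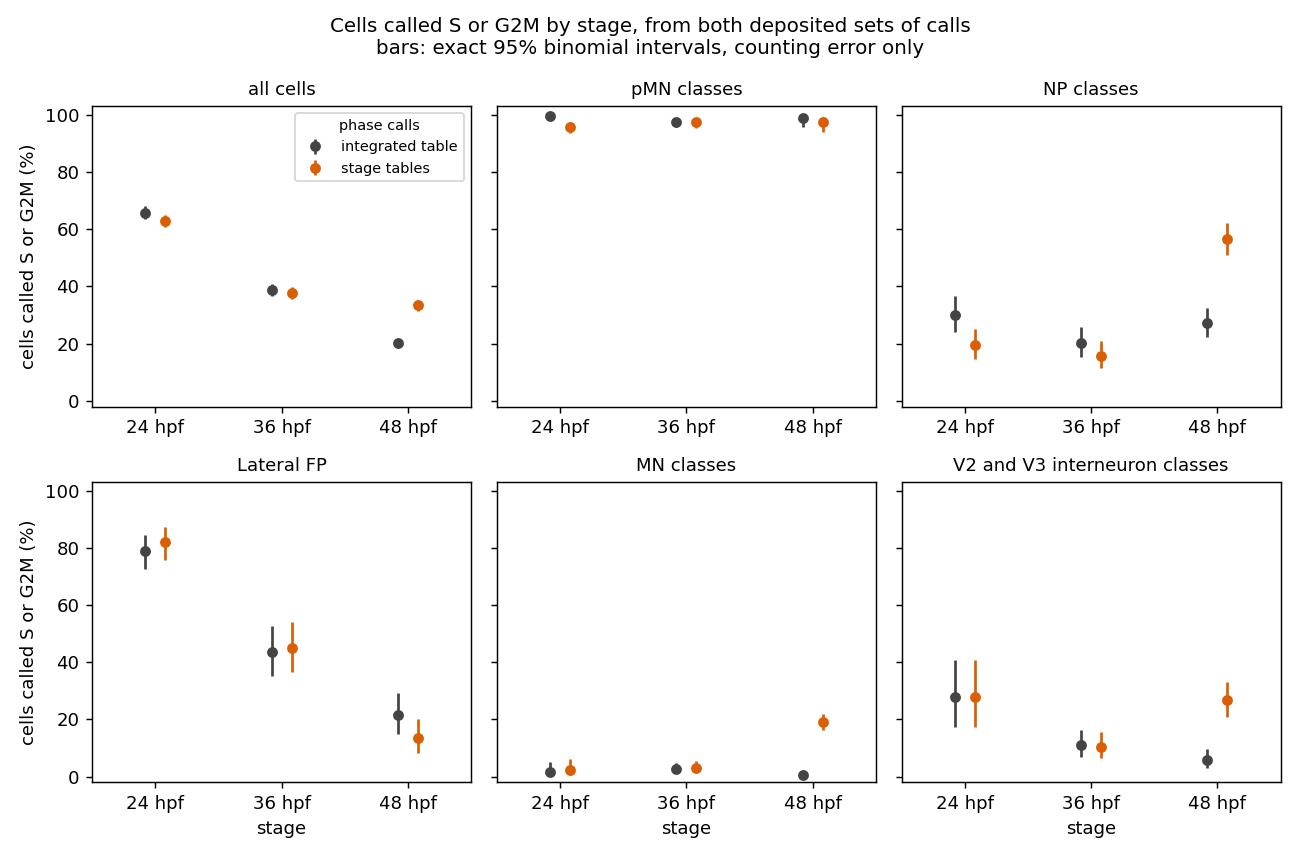
Percent of cells called S or G2M (y axis) at 24, 36 and 48 hpf (x axis) for all cells and 5 groups of classes, with the calls of the integrated table in grey and those of the stage tables in orange; bars are exact 95% binomial intervals, which cover counting error only. The sets of calls differ mainly at 48 hpf, where the motor neuron classes are at 0.615% by the integrated table and 18.9% by the stage table.

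Progenitor classes, taken as the 8 classes whose deposited name says progenitor, precursor, pMN or radial glia, were mostly called S or G2M at each stage. Their share of the sorted cells was smaller at each later stage. They were 43.9% of the cells at 24 hpf (802 cells), 31.0% at 36 hpf (633 cells) and 12.1% at 48 hpf (289 cells). Among them 96.8% (95.3 to 97.9), 87.2% (84.3 to 89.7) and 93.1% (89.5 to 95.7) were called S or G2M at the 3 stages. The lower value at 36 hpf came with CMN Precursor, of which 88.2% (97 of 110 cells) was called S or G2M at 24 hpf and 36.0% (27 of 75, 25.2 to 47.9) at 36 hpf. NM Progenitor at 24 hpf stood at 90.6% (87 of 96) and Retinal Progenitor at 36 hpf at 86.1% (87 of 101). By the stage tables the shares of the progenitor classes were 94.1%, 85.9% and 70.6%, so that the order of 36 and 48 hpf depended on which calls were used. That order also depended on the classes taken: with NP, Pre-OPC and OPC added, the integrated calls gave 82.5%, 65.8% and 50.6%. Since pMN1 and pMN2 held no G1 cell, class and phase were not independent in this annotation, and with free RNA and depth left open the calls alone do not show that a cell was dividing.

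Each cell carried a class name from the table of its own stage and one from the integrated table, which asks how far the shares rest on the annotation. Leaving out closing numbers, the names were the same for 76.2% of the 24 hpf cells (74.2 to 78.1), 79.8% of the 36 hpf cells (78.0 to 81.6) and 78.6% of the 48 hpf cells (76.9 to 80.2). With the numbers, 42.0%, 53.7% and 45.9% had the same name, and the adjusted Rand index, which is 1 for identical groupings and near 0 for unrelated ones, was 0.506, 0.542 and 0.568. OPC and Pre-OL were nearly the same cells in both 48 hpf annotations: 124 of the 131 stage-table OPC cells and 70 of the 73 Pre-OL cells kept the name. RG was not: of 218 stage-table RG cells, 111 were NP1, 62 RG and 26 pMN2 in the integrated table. Of the 90 stage-table MEP Glia cells, 47 were pMN2, 20 pMN1 and 20 MEP Glia. Of the 81 cells called CMN Precursor at 48 hpf, 48 were CMN and 31 MEP Glia. Of the 178 stage-table Pre-MN cells at 24 hpf, 88 were NP2 and 31 Pre-MN. The stage-table names of MN5 cells differed by stage: 27 of 29 at 24 hpf and 42 of 45 at 36 hpf were GABAergic IN. At 48 hpf 223 of 238 MN5 cells were MN4. The 48 hpf stage table did not use the name GABAergic IN, so whether the cells themselves differed cannot be told from the names. Without MN5, the MN share was 6.19%, 15.3% and 24.0% at the 3 stages, and 3.88-fold higher at 48 than at 24 hpf (3.17 to 4.79).

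**Figure D3:**
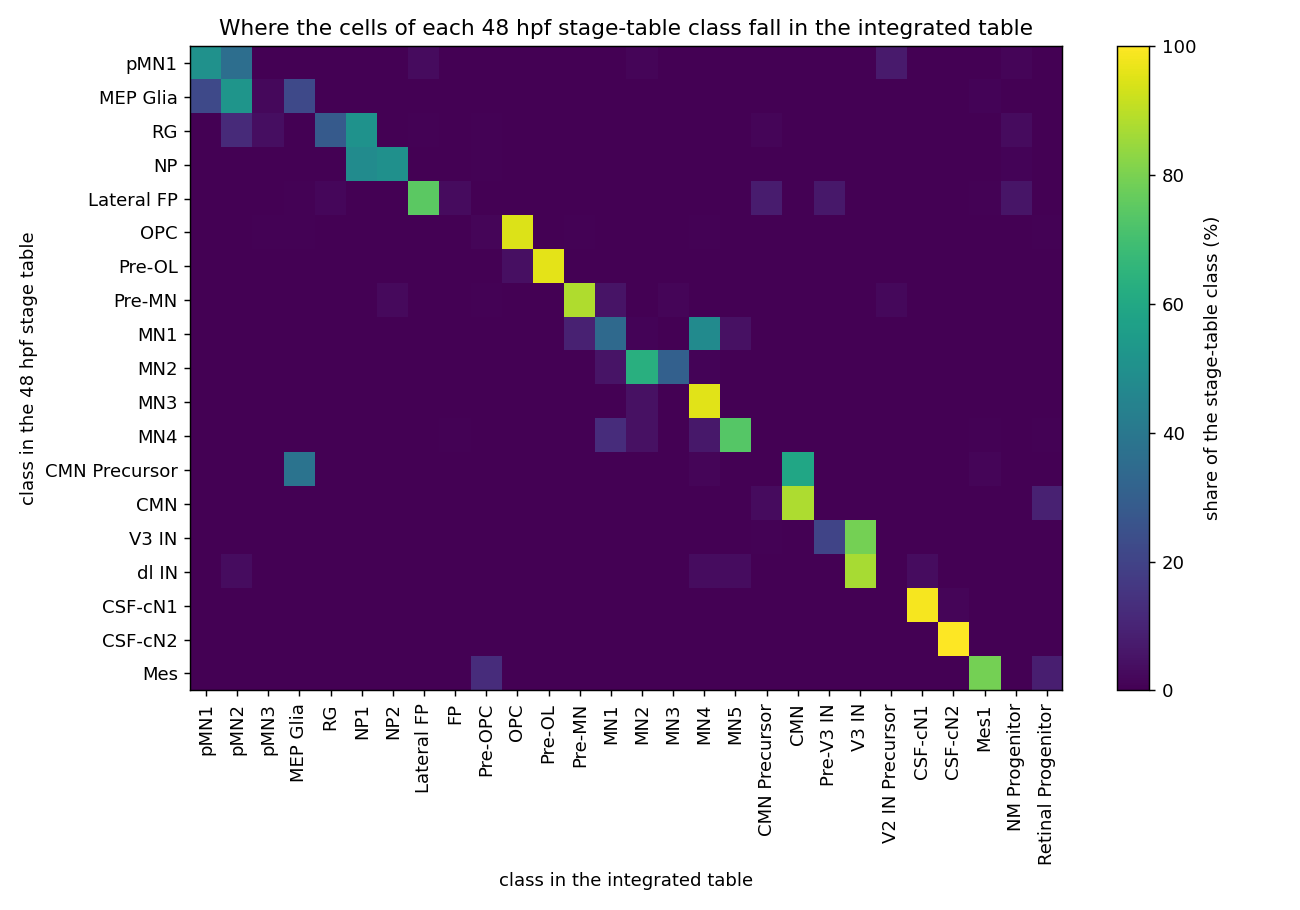
For each class of the 48 hpf stage table (y axis), the percent of its cells (colour, 0 to 100) that fell in each class of the integrated table (x axis), in 1 library of 2394 cells. OPC, Pre-OL and both CSF-cN classes map onto the class of the same name, while RG cells fall mostly in NP1 (50.9%) and MEP Glia cells mostly in pMN2 (52.2%).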

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

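Matching all cells on UMI depth was fixed before the data were examined, and the other tests in this part, and the use of matching against these patterns, were chosen after the results were seen. Among the cell barcodes, which the comparisons of shares did not use, 87.0% of the 48 hpf cells (2082 of 2394, 85.6 to 88.3) had a first stretch of 7 bases that occurred in neither other library, whereas 97.4% of the 36 hpf cells had a start seen at 24 hpf. In the cluster numbers of the stage tables, which run by falling size from 0, number 7 had no cell at 24 hpf and number 13 had none at 36 hpf, while no number was absent at 48 hpf. If a cluster was taken out, the sizes of its neighbours would put it at 123 to 130 cells at 24 hpf and 44 to 92 cells at 36 hpf, and whether any was taken out is not given in the sources used here.

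OPC, Pre-OL and RG cells were almost all at 48 hpf, with 2, 9 and 262 cells at 24, 36 and 48 hpf. The tables argue against too few UMIs per cell as the cause: in the middle range of depth of these classes at 48 hpf, 6220.5 to 9421.75 UMIs, they were 0 of 596 cells at 24 hpf (0%, upper limit 0.617), 0.796% of 377 cells at 36 hpf (upper limit 2.31) and 22.1% of 588 cells at 48 hpf (18.8 to 25.7). This range was set by the 48 hpf cells of these classes, which raises their share there above the 10.9% of all 48 hpf cells. It leaves gene detection open, since cells of 5000 to 6000 UMIs had a median of 1813 genes at 48 hpf against 1536 at 24 hpf and 1506.5 at 36 hpf. The barcode set stays open, because 87.0% of the 48 hpf cells had starts seen in neither earlier library and each stage has 1 library, so barcode set and stage cannot be told apart. A biological change between 36 and 48 hpf also stays open, as a hypothesis that these libraries did not test.

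The pMN share went from 31.1% to 7.02% between 24 and 48 hpf. Whether a loss of all cells called S or G2M in equal proportion made the step from 36 to 48 hpf is not decided by the next values. By the integrated calls the pMN share of such cells was 51.5% at 36 hpf (48.0 to 55.1) and 34.5% at 48 hpf (30.3 to 38.9). By the stage-table calls, cells of the pMN classes were 406 of 771 such cells at 36 hpf and 164 of 799 at 48 hpf. RG and MEP Glia held 4 and 15 such cells at 36 hpf and 64 and 53 at 48 hpf by the integrated calls. Cells added in these classes lower the pMN share of such cells even where losses are equal. The stage-table calls also took in 11 cells of the MN classes at 36 hpf and 154 at 48 hpf. The intervals cover counting error only, with a single library per stage. For the step from 24 to 36 hpf, the pMN share of such cells by the integrated calls was 46.9% at 24 hpf and did not fall. A share that does not fall decides nothing, because pMN1 and pMN2 held no G1 cell. The share of all cells called S or G2M also turned at matched depth (55.3% at 24 hpf and 59.7% at 36 hpf). Cells matched on UMI depth gave a pMN share of 22.1% at 24 hpf and 7.89% (6.19 to 9.87) at 48 hpf. Within counting error and for a single draw of matched cells, this argues against UMI depth as the whole cause between these stages. pMN cells were deeper than the library median at 48 hpf too (10103.5 against 5774.5 UMIs). The barcode set and the age of the embryos stay open between 24 and 48 hpf. Between 24 and 36 hpf depth cannot be told apart from stage: matched cells gave 33.7% at 36 hpf, above the 24 hpf value, and pMN cells were deeper than the library median at both stages (10954 against 8935.5 UMIs and 6787 against 4569), so matching drew more of them from the shallower library.

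The CSF-cN share was lowest at 36 hpf, 1.86%. The next values are shares of G1-called cells, not of all cells. Before matching, CSF-cN cells were 112 of 624 G1-called cells at 24 hpf, 37 of 1254 at 36 hpf and 120 of 1913 at 48 hpf. G1-called cells matched on depth gave 3.69% at 36 hpf (12 of 325, 1.92 to 6.36) and 16.9% at 24 hpf (13.0 to 21.5). Within counting error these values argue against UMI depth as the whole cause of the difference from 24 hpf. Against 48 hpf the same test left depth open, with 7.69% (25 of 325, 5.04 to 11.1) at 48 hpf and intervals that overlap. Matching all cells kept the log2 ratio of 48 over 36 hpf (1.47, and 1.45 before), but nearly all CSF-cN cells were called G1 and matching left 59.7% of the 36 hpf cells and 23.4% of the 48 hpf cells called S or G2M, so this value does not decide. A cluster taken out of the 36 hpf table could also account for the pattern: if up to 92 such cells had all been CSF-cN, the share would have been 6.09% (5.11 to 7.19), and nothing in the tables says whether there were such cells, while a biological difference between stages was not tested beyond this.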

How the results depend on the processing

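Matched UMI depth, the stage annotation and phase calls, and the other settings named first were fixed before the data were examined; the score limit on stage-table calls, the wider progenitor group and the alternatives on MEP Glia and MN5 were chosen after seeing the data. Of 389 log2 ratios of shares under alternatives, 358 kept their call or lack of one, 11 lost the call, 14 gained one in the same direction and 6 turned with a call before or after. Some could not change, because MEP Glia inside CMN Precursor alters only those names and leaves the ratios of all others as they were. The neural or glial denominator shifts all ratios of a pair of stages by the same amount. The 358 therefore overstate how far the calls were put to the test. Of the 358, 15 changed sign without a call under either setting, among them pMN at 36 over 24 hpf (-0.61 to 0.61) and NP at 48 over 24 hpf (0.03 to -0.80) with matched depth. The causes were not tested. Calls gained included -1.04 for CSF-cN at 48 over 24 hpf and 1.46 for MN and 1.09 for Pre-MN at 48 over 36 hpf with matched depth, 1.08 for MN at 48 over 36 hpf and -4.42 for V2 IN Precursor at 48 over 24 hpf with stage-table names, -1.84 for V2 IN Precursor at 48 over 36 hpf with at least 2000 UMIs, and 1.23 for Pre-V3 IN at 48 over 24 hpf with the mitochondrial limit. With stage-table names the ratio was -0.55 for Pre-MN at 36 over 24 hpf, -0.64 for Pre-MN at 48 over 24 hpf, -4.19 for V2 IN Precursor at 36 over 24 hpf and 2.77 for Mes at 48 over 36 hpf. With matched depth it was -1.51 for NP and -0.12 for Pre-MN at 36 over 24 hpf. Counts of names were taken over 20 families of classes in the integrated table and 21 in the stage tables. Those lower at 36 than at 24 hpf were 2, but 4 by stage-table names and 1 with the neural or glial denominator. That denominator leaves out Mes and NM Progenitor, whose call was among the 2, so no call was lost there. Those lower at 48 than at 24 hpf were 4, but 7 by stage-table names. The other 39 of 42 counts, which include those same settings, stayed within 1.5 times.

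Shares called S or G2M at 24, 36 and 48 hpf were 55.3%, 59.7% and 23.4% with matched depth, 61.6%, 36.3% and 15.1% with a score above 0.1, and 58.1%, 35.0% and 11.5% with such a score in the stage tables. Stage-table calls gave 62.9% and 33.4% at 24 and 48 hpf. Leaving out the cells with the most UMIs gave 36.2% at 36 hpf, and the mitochondrial limit 22.1% at 48 hpf. Among progenitor classes, matched depth gave 95.2% at 24 hpf and 93.4% at 36 hpf. A score above 0.1 gave 94.4% and 82.7% at 24 and 48 hpf, stage-table calls 94.1% and 70.6%, and both together 89.0% and 64.7%. With NP, Pre-OPC and OPC added the shares were 82.5%, 65.8% and 50.6%. On their own, pMN1 and pMN2 were at 100% at all 3 stages, pMN3 at 98.6%, CMN Precursor at 88.2% and NM Progenitor at 90.6% at 24 hpf, CMN Precursor at 36.0% at 36 hpf, and RG at 98.5% at 48 hpf. Median UMIs at 24, 36 and 48 hpf were 9288.5, 4763 and 5967 with at least 2000 UMIs and 8754, 4437 and 5577 without the deepest cells, and 9174 and 4669.5 at 24 and 36 hpf with the mitochondrial limit. Median genes were 2092, 1399 and 1985, then 2019, 1320 and 1893, then 2082 and 1376 under the same settings. The share of cells with the same name in both tables stayed within its interval under all 9 alternatives.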

Other observations

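Most of the deepest cells at 48 hpf were MN4 or MEP Glia, a point looked at only after the data were seen, like all others in this part. At 48 hpf 83 cells had over 20000 UMIs, of which 42 were MN4 and 17 MEP Glia, against 29 such cells at 24 hpf and 13 at 36 hpf. At the earlier stages pMN3 held the most of them, 11 at 24 hpf and 6 at 36 hpf. The deepest cell, an MN4 cell at 48 hpf, had 172754 UMIs and 8404 detected genes. The median MN4 cell at 48 hpf had 9200.5 UMIs and the median MEP Glia cell 12594, against 5774.5 in the whole library. Whether these cells include doublets was not tested, since the tables hold no values per gene.

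GABAergic IN was a name of the earlier stage tables only, with 57 cells (3.12%) at 24 hpf and 44 (2.15%) at 36 hpf. At 24 hpf 27 of these cells were MN5 and 23 V3 IN in the integrated table. At 36 hpf 42 of them were MN5. The name dl IN was given to 28 cells at 36 hpf and 31 at 48 hpf, of which 23 and 27 were V3 IN in the integrated table. The 24 and 36 hpf libraries shared 7 full cell barcodes, and neither shared any with the 48 hpf library.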
